A study of Mus musculus with 48 samples.

How the data were processed

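tRNA was sequenced in 48 libraries from brain, intestine, kidney and liver of germ-free (GF) and specific-pathogen-free (SPF) mice, with 3 replicates for each of the 16 combinations of tissue, colonization and demethylase treatment. Per the labels, treated and untreated portions came from the same RNA sample, 150 ng of tRNA entered reverse transcription with a thermostable enzyme, and cDNA was circularized and amplified in 12 PCR cycles. Brain and kidney libraries carried the same 12 index sequences, and intestine and liver libraries another set of 12. Lanes and run dates are not given in the sources used here, so batches could not be tested apart from tissue.

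The values per library are in RPKM, deposited by the authors per kilobase of tRNA and scaled to the mapped molecules of the same compartment, with nuclear-encoded and mitochondrially encoded tRNAs each scaled to their own total. The mapping table deposited by the authors holds counts of reads and molecules per library. The aligner, its version, the genome build and the rule by which reads became molecules are not given in the sources used here, so no coordinates are printed. Feature names and gene IDs are those of the authors' gene list, and 226 of the 238 IDs were found in a mouse RefSeq table by ID. Multiplying each value by tRNA length and compartment total gave whole molecules within 0.001 for every feature in 47 of 48 libraries. In treated kidney GF replicate 1 the mitochondrial values needed a total 2 times that of the mapping table, and its mitochondrial molecules were recovered on that basis. A single value of -1 molecules, Leu-TAA-3 in treated liver SPF replicate 3, was set to 0. The total reads of all 48 libraries are even numbers, so the mapped share of reads may be counted on a scale of read mates and is compared between libraries only.

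Libraries held 25798 to 58838854 molecules. PCR copies are not independent molecules where they were not removed, so intervals and floors cover counting error only. In the shallowest library the mitochondrial share of 33.14% had a 95% Wilson interval of 32.57% to 33.72%, and a count of 0 allowed a share of up to 0.011629% (3 molecules). The number of features at 0 ran from 5 to 38 per library. Replicates correlated across features at 0.812 to 0.999, with a median of 0.990 in untreated and 0.964 in treated libraries, where features are not independent replicates. Every 1 of 48 pairs of replicates differed by more than counting error, with a chi-square of at least 39.78 per degree of freedom.

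Before the data were examined, edgeR on counts had been chosen for the main tests, along with the comparisons, the lists, the naming rule and most alternatives. Because the values proved to be RPKM, the main test became limma with a mean-variance trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1000), for features with a mean of at least 2000 RPKM in the libraries of the fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. GF was compared with SPF in a fit of 8 groups for the 24 treated libraries and another for the 24 untreated ones. Treated and untreated libraries and their interaction with colonization were compared in 1 fit of 12 libraries per tissue, and tissues in the 12 treated SPF libraries of the treated fit by a joint test and by each tissue against the mean of the other 3. The difference of the GF effect between tissues was tested jointly. Anticodon values were summed over isodecoders, giving 71 sums.

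Lists were fixed by anticodon or compartment: mitochondrially encoded, queuosine, inosine, mcm5s2U, m1G37, m3C32, long variable arm, branched-chain, essential amino acids, initiator methionine, selenocysteine and Arg-TCT. The long variable arm list takes all nuclear-encoded serine, leucine and selenocysteine tRNAs, whatever their length. Lists were tested with camera at a preset correlation of 0.01 over 44 tests per comparison. The selenocysteine list has 1 member, fewer than the 3 needed, so only its values are given. Shares, the effective number of features (the exponential of the Shannon entropy), molecules and mapped shares were compared by two-sided permutation tests stratified by tissue, or by tissue and colonization, with 100000 resamples (smallest possible p 1e-05) in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

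Features named are those with a mean of at least 100 molecules: up to 6 each way in treated GF against SPF libraries, past the threshold, with the largest change and with all 3 GF libraries on 1 side of the 3 SPF libraries; up to 5 each way in other comparisons and for anticodons; up to 4 members with the smallest p in a list described; and the 3 with the smallest p where fewer than 3 passed. Features outside this rule are named only where said to be chosen after their values were seen.

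Replicate numbers were taken to link a treated and an untreated library of the same RNA sample. Counts with a block for them are given where the block changed a result. GF and SPF libraries share a number only, so that block is an alternative. Over 24 pairs of treated and untreated libraries, residuals had a median correlation of 0.16, and 11 pairs were best matched by their own number. In intestine these correlations were 0.17, -0.09 and -0.25 in SPF and -0.14, -0.28 and -0.17 in GF. The values do not show the link there, on which the sign-flip tests and the block by RNA sample rest. Over 24 pairs of GF and SPF libraries the median was 0.01. In untreated intestine the GF and SPF libraries of the same number correlated at 0.36, 0.44 and 0.64, each best matched by its own number, and the block gave 79 calls there against 78. The labels do not say that numbers pair GF with SPF. A score placed each library between the untreated and the treated profile of its tissue, near 1 for untreated libraries and near 0 for treated ones. By it, 5 libraries lay past 0.5 on the side of the other state (treated above it, untreated below it): brain SPF treated replicate 3 (0.54), kidney SPF treated replicate 1 (0.80), liver GF treated replicate 2 (1.10), intestine GF untreated replicate 3 (0.31) and liver GF untreated replicate 1 (0.49). Untreated brain GF replicate 1 (0.55) and untreated intestine GF replicate 2 (0.58) lay close to 0.5 on their own side and were not among the 5.

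Alternatives chosen beforehand were edgeR 4.0.16 on recovered molecules with RLE factors or library totals, DESeq2 1.42.0, no filter on low values, the replicate block, each tissue alone, mitochondrially encoded tRNAs left out, and each library left out in turn. Lists had camera with an estimated correlation, fry and library totals, and shares had a minimum mean count of 10 and a difference of medians. Chosen after seeing the data were TMM factors, pseudocounts of 100 and 5000 RPKM, libraries centred at their median, array weights, leaving out the 5 libraries above, in the joint fit or in each tissue alone, the mitochondrial total of the mapping table, and the queuosine share of nuclear-encoded molecules.

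The tests were tried on simulated counts with 20 features changed 2-fold and 20 others changed 4-fold in the same run. Of these, treated GF against SPF brain recovered 6 at 2-fold and 17 at 4-fold with 0 false calls, untreated brain 12 and 16 with 5 false calls, treated against untreated kidney 19 and 20 with 4, and the tissue test 5 and 17 with 2. In a simulation with the queuosine and m1G37 lists changed 2-fold, camera called both, and also 2 of the 9 other lists. Several of those 9 share members with the changed lists, so the 2 further calls need not be false. Modification sites and misincorporation, which the series also concerns, were not analysed here.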

Results

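Transfer RNAs were sequenced from brain, intestine, kidney and liver of male C57BL/6 mice that were 4 weeks old. The mice were either germ-free (GF) or carried a microbiota under specific-pathogen-free housing (SPF). Gel-purified tRNA of each RNA sample was divided: 1 portion was treated with the AlkB demethylases, which remove base methylations that stop reverse transcription, and 1 portion was left untreated. The 48 libraries form 16 groups of 3, given by tissue, colonization and treatment. Values were present for 238 tRNA features, of which 216 are nuclear-encoded and 22 are mitochondrially encoded (prefix M-). A feature is 1 tRNA of the gene list, named by amino acid, anticodon and a running number. Libraries held from 25798 to 58838854 tRNA molecules. The treated SPF libraries of liver (25798 to 197369 molecules) and intestine (70051 to 544433) were the shallowest groups. Their GF counterparts held 313426 to 3876657 molecules in liver and 6839714 to 10109370 in intestine. In 5 libraries the profile lay past the midpoint toward the other treatment state of the same tissue: treated brain SPF replicate 3, treated kidney SPF replicate 1, treated liver GF replicate 2, untreated intestine GF replicate 3 and untreated liver GF replicate 1. They were kept in the main comparisons. The labels do not say whether replicates are separate animals, so p-values measure the spread between libraries. In limma that spread was pooled over all groups of a fit, so tissues with tight and loose replicates share an estimate per feature. Features with near-identical sequences can share molecules, which leaves the values of single isodecoders uncertain. Log2 changes were taken after adding 1000 RPKM, which understates changes of low features, and kRPKM stands for 1000 RPKM.

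The comparison of GF with SPF libraries addresses the question named in the series title, whether the microbiome changes host tRNAs in a tissue-specific way. In treated liver libraries, 41 of 188 tested features were lower in GF and 0 were higher. Glu-CTC-2 (gene ID 102467518) showed the largest drop, from 53.7 ± 43.7 kRPKM (SD, n = 3) in SPF to 3.28 ± 1.25 (SD, n = 3) in GF, a log2 change of -3.36 ± 0.48 (SE; adjusted p = 4.28e-05). Leu-CAG-4 was 5.34-fold lower in GF (adjusted p = 0.00102), and Ser-GGA-1 was 4.31-fold lower (adjusted p = 0.000978). Gly-CCC-2 and Gly-CCC-4 were 4.66-fold and 4.26-fold lower. Met-CAT-5 was 4.78-fold lower (adjusted p = 0.0361), and this call was lost in 12 of the 20 alternatives run on it, among them the fits without any 1 liver library except SPF replicate 3. The call of Gly-CCC-4 was lost in 6 of 20, among them the fit without GF replicate 2. Among these 6 features, Glu-CTC-2 alone stayed past the threshold in every alternative. The median change of all tested features was -0.30 under the authors' scaling and 0.21 under TMM, and the sides shifted with it. TMM called 6 higher and 18 lower, RLE 2 and 23, DESeq2 10 and 37, library totals 0 and 42, and centring each library at its median 3 and 14. A fit to the 6 liver libraries alone called 5 features, all lower, and without SPF replicate 1, the shallowest library, 20 were called. These 6 features averaged 203 to 415 molecules per library, so counting error adds to the spread.

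Brain, intestine and kidney had no feature past the threshold in treated libraries. In brain, Met-CAT-1 (1.05 ± 0.30 on the log2 scale, SE), M-Ile-GAT (1.04 ± 0.32) and His-GTG-2 (0.90 ± 0.29) had the smallest p-values, each with an adjusted p of 0.244 in limma. In intestine, Asn-GTT-1 was lower in GF by 1.09 ± 0.57, Ala-AGC-5 by 0.70 ± 0.40 and Thr-TGT-1 by 0.61 ± 0.33, with an adjusted p of 0.998 for each. In kidney, M-Lys-TTT was higher by 1.03 ± 0.39 and M-Pro-TGG by 0.81 ± 0.35, while M-Trp-TCA was lower by 0.84 ± 0.44 (adjusted p = 0.964 for each). Beside the 0 calls of limma, 17 features in brain, 0 in intestine and 2 in kidney had an unadjusted p under 0.05. The counts by edgeR and DESeq2 were 0 in each of these tissues. Weighting libraries by their quality called 71 features in brain, 41 higher and 30 lower, and 4 in kidney. Fitting the brain libraries alone without SPF replicate 3, which resembled untreated libraries, called 12. On simulated counts of this design, 6 of 20 changed features were recovered at a 2-fold change in brain and 17 of 20 at a 4-fold change, so most changes of 2-fold could have been missed there. Intestine and kidney were not simulated for this comparison.

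Values were also summed per anticodon, which does not depend on how molecules were shared between isodecoders. Among the liver anticodons named here, Pro-TGG alone sums several features, and the others restate single features. Glu-CTC, Leu-CAG, Gly-CCC and Met-CAT, which hold other features named above, are not among them. Ser-GGA was 4.31-fold lower in GF (log2 -2.11 ± 0.40, SE; adjusted p = 0.000959) and M-Ser-GCT was 5.64-fold lower (adjusted p = 0.0198). M-Asn-GTT, Pro-AGG and Pro-TGG were 2.54-fold, 2.26-fold and 2.25-fold lower, each with an adjusted p of 0.0153. In all, 7 of 71 anticodons passed in liver, all lower, while brain, intestine and kidney had 0. Brain had 2 when fitted alone, 21 when fitted alone without SPF replicate 3 and 29 with array weights, and liver had 2 when fitted alone and 0 when fitted alone without GF replicate 2. In brain, Lys-CTT (1.03 ± 0.30), M-Ile-GAT (1.04 ± 0.32) and His-GTG (0.90 ± 0.30) came closest, at adjusted p of 0.12 to 0.144. In intestine, Pro-AGG, Arg-ACG and Pro-CGG had an adjusted p of 0.999 each, and in kidney M-Lys-TTT, M-Pro-TGG and M-Trp-TCA had 0.94. At an unadjusted p under 0.05 limma had 7 anticodons in brain, 0 in intestine and 2 in kidney, and edgeR and DESeq2 called 0 in each. M-Ser-GCT lost its liver call without GF replicate 2 or SPF replicate 2 or 3, M-Asn-GTT without GF replicate 2, and Pro-AGG without SPF replicate 1. In liver, TMM called 1 anticodon and centred libraries called 3. Without GF replicate 1 the liver count was 12, and without SPF replicate 3 it was 11.

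In untreated libraries, where methylated tRNAs stop reverse transcription early, GF and SPF differed in brain, intestine and liver. In brain, Asp-GTC-2 rose from 21.4 ± 4.77 kRPKM (SD, n = 3) in SPF to 69.1 ± 6.06 in GF, a log2 change of 1.67 ± 0.25 (SE; adjusted p = 4.37e-05). Lys-CTT-14 (2.84-fold), Met-CAT-3 (2.71-fold), Gly-TCC-1 (2.56-fold) and Asp-GTC-1 (2.43-fold) were also higher in GF brain. Lys-CTT-14 lost its call in DESeq2 and in edgeR with TMM, RLE or library totals, Asp-GTC-1 with TMM or RLE, and Gly-TCC-1 with TMM. M-Leu-TAA was lower, at 387 ± 26.9 kRPKM (SD) against 1120 ± 127, as were Ser-AGA-2 (log2 -1.31 ± 0.17, SE; adjusted p = 1.15e-05), Ser-TGA-2, Ser-AGA-1 and Ile-AAT-1. The log2 change of M-Leu-TAA was -1.53, and its call was lost with library totals as scaling. In total 44 brain features were higher and 23 lower of 177 tested, with a median change of all features of 0.33. The side again followed the scaling: TMM, whose median was 0.02, called 26 higher and 47 lower, DESeq2 30 and 52, RLE 30 and 47, library totals 40 and 33, and centred libraries 15 and 40. Without SPF replicate 3 the count fell to 44.

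Untreated intestine had 53 features higher and 25 lower in GF. Leu-CAA-4 (gene ID 108168133) rose from 33.1 ± 3.72 to 137 ± 9.9 kRPKM (SD, n = 3), a log2 change of 2.02 ± 0.16 (SE; adjusted p = 7.74e-09). Tyr-GTA-5 rose from 1.89 ± 0.484 to 12.5 ± 5.55 kRPKM (adjusted p = 3.93e-07). Met-CAT-5 was 5.94-fold higher, Gln-TTG-5 4.17-fold and Glu-CTC-2 3.79-fold. Gly-GCC-2 was 2.93-fold lower, Val-CAC-4 2.57-fold, Ser-GCT-4 2.53-fold and Lys-CTT-3 2.33-fold, and iMet-CAT-1 fell from 510 ± 82.2 to 215 ± 65.5 kRPKM (adjusted p = 0.00096). The call of Val-CAC-4 was lost without GF replicate 1. With centred libraries, 24 features were higher and 38 lower, with RLE 44 and 33, and with TMM 49 and 31.

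In untreated liver, M-Ser-GCT fell from 130 ± 32.5 kRPKM (SD, n = 3) in SPF to 19.3 ± 22.3 in GF, a log2 change of -3.35 ± 0.62 (SE; adjusted p = 0.000872). Val-AAC-4 (3.06-fold), Val-CAC-3 (3.01-fold), Ala-TGC-1 (2.80-fold) and Gly-GCC-1 (2.79-fold) were lower as well. Gly-GCC-1 lost its call in 5 of 20 alternatives, namely DESeq2, edgeR with TMM, RLE or library totals, and liver alone, where M-Ser-GCT lost its call too. Ser-GGA-1, Ile-AAT-3, Met-CAT-1, Val-AAC-5 and Val-AAC-1 were higher, by 1.45, 1.06, 0.82, 0.72 and 0.70 on the log2 scale. Ser-GGA-1, Val-AAC-5 and Val-AAC-1 no longer passed without GF replicate 1 or without any 1 of the SPF replicates. The 43 called features divided into 8 higher and 35 lower under the authors' scaling, with a median of -0.14. Under RLE they were 31 and 18, under TMM 37 and 13, under DESeq2 44 and 19, under library totals 23 and 19, and with centred libraries 15 and 18. Liver alone gave 9 calls, and without SPF replicate 3 the joint fit gave 26. In untreated kidney, only M-Thr-TGT passed, at 635 ± 34.9 kRPKM (SD, n = 3) in GF and 387 ± 13.7 in SPF (log2 0.71 ± 0.16, SE; adjusted p = 0.0418). Met-CAT-1 was higher by 0.61 ± 0.22 and M-Leu-TAA lower by 0.70 ± 0.25, with an adjusted p of 0.684 each. Leaving out any 1 of the 6 kidney libraries gave 0 calls in limma, and in the complete fit 9 features had an unadjusted p under 0.05 while edgeR and DESeq2 called 1 each. A fit to kidney alone called 44, 16 higher and 28 lower.

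**Figure D1:**
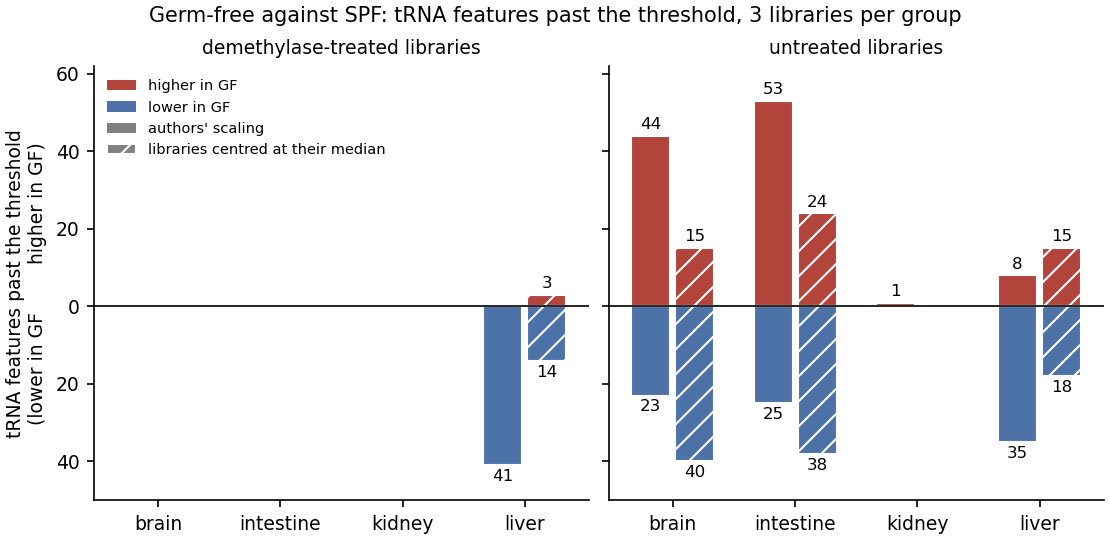
Bars count tRNA features past an adjusted p of 0.05 in GF against SPF libraries, by tissue and treatment (3 libraries per group), above 0 for features higher in GF and below 0 for features lower in GF. Plain bars use the authors' scaling and hatched bars use libraries centred at their median: in untreated brain 44 higher and 23 lower became 15 and 40.

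The demethylase comparison asks which tRNAs gain or lose reads when methylations are removed. In brain, Asn-GTT-3 was higher in treated libraries by 2.26 ± 0.22 (log2, SE; adjusted p = 2.77e-05), as were Val-CAC-4 (4.91-fold), M-His-GTG (4.83-fold), iMet-CAT-1 (4.19-fold) and iMet-CAT-2 (3.70-fold). Met-CAT-5 was 11.2-fold lower, and Tyr-GTA-5, Ser-GGA-1, Glu-CTC-2 and Gln-TTG-5 were 2.64-fold to 3.34-fold lower. Kidney had Asn-GTT-3 (4.14-fold), M-His-GTG (3.96-fold), Cys-GCA-8 (3.96-fold), Asp-GTC-4 (3.62-fold) and Lys-TTT-2 (3.42-fold) higher, and Met-CAT-5 (5.42-fold), Leu-TAA-1, Met-CAT-3, Gly-GCC-4 and Gln-CTG-2 lower. In intestine the named features went the other way for several of these tRNAs. Met-CAT-5 was 3.64-fold higher and Tyr-GTA-5 3.13-fold higher in treated libraries, next to Gly-ACC-1 (3.96-fold), Ser-GGA-1 (3.31-fold) and Lys-CTT-14 (3.17-fold). iMet-CAT-1 was 3.36-fold lower there, with Asn-GTT-1 (5.24-fold), M-Asp-GTC (4.53-fold), Glu-CTC-1 (3.57-fold) and M-Ile-GAT (3.18-fold). Liver had iMet-CAT-3 (4.66-fold), Gly-ACC-1 (4.39-fold), Gly-CCC-4 (3.67-fold), iMet-CAT-2 (3.55-fold) and Gly-CCC-3 (3.17-fold) higher, and Glu-CTC-1, Gly-GCC-4, Lys-CTT-3, Ala-AGC-2 and Glu-TTC-1 lower by 1.82, 1.74, 1.22, 1.17 and 1.08 on the log2 scale. Of the liver features, Ala-AGC-2 lost its call in 10 of 24 alternatives, Gly-CCC-3 in 6, Gly-CCC-4 in 4 and iMet-CAT-3 in 2, among them the fit without GF treated replicate 1 for each.

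In brain 65 features were higher and 53 lower of 171, in intestine 62 and 43 of 179, in kidney 95 and 59 of 188, and in liver 27 and 9 of 178. The medians of all features were 0.20, 0.04, 0.23 and 0.20 under the authors' scaling, and 0.46, 0.44, 0.35 and 0.93 with library totals. Library totals gave 105 higher and 52 lower in brain, 101 and 34 in intestine, and 92 and 16 in liver. TMM gave 84 and 91 in kidney, 62 and 56 in intestine, and 36 and 26 in liver. Centred libraries gave 48 and 61 in intestine and 8 and 13 in liver, RLE 90 and 82 in kidney and 34 and 30 in liver, and DESeq2 90 and 85 and 43 and 32 in these tissues. Leaving out 1 library moved the liver count of 36 by more than 1.5 times for 8 of the 12 libraries. It was 16, 20 and 18 without untreated SPF replicates 1, 2 and 3, 18 and 23 without untreated GF replicates 2 and 3, and 13, 57 and 14 without treated GF replicates 1, 2 and 3. With treated and untreated libraries of the same RNA sample paired by a block, 116 features were called in brain, 97 in intestine, 153 in kidney and 46 in liver.

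**Figure D2:**
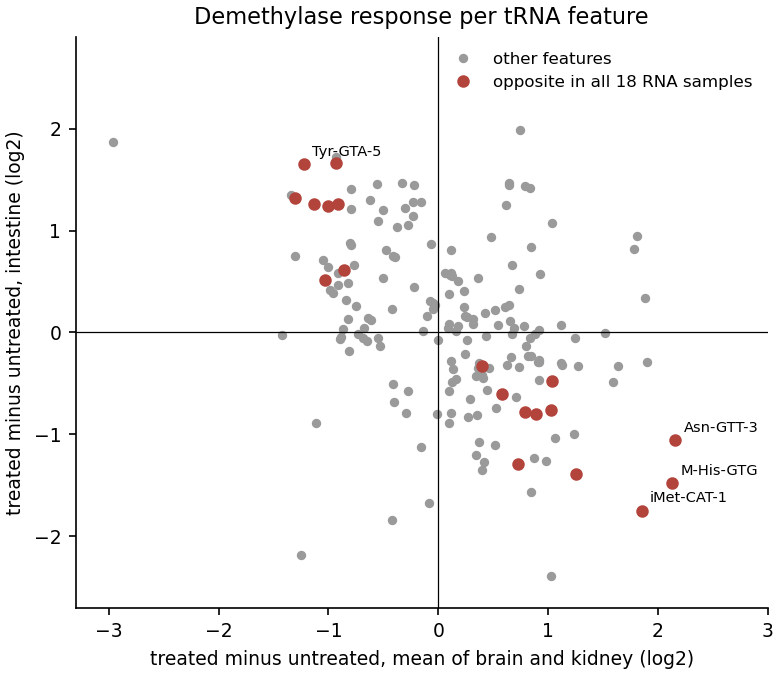
Each point is 1 of 184 tRNA features, with its treated minus untreated difference in log2(RPKM + 1000) as the mean of brain and kidney on the horizontal axis and in intestine on the vertical axis. The 19 features in red moved in opposite directions in all 18 RNA samples, among them M-His-GTG and iMet-CAT-1.

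The interaction of colonization and demethylase asks whether the treatment changed GF and SPF libraries by different amounts. In intestine, Leu-CAA-4 gained less in GF than in SPF, by a log2 difference of -1.85 ± 0.26 (SE; adjusted p = 0.000823), and was at 137 ± 9.9 kRPKM (SD, n = 3) untreated and 173 ± 23.7 treated in GF, against 33.1 ± 3.72 and 153 ± 6.82 in SPF. Met-CAT-5 (-2.54 ± 0.58), Tyr-GTA-5 (-1.95 ± 0.44), Gln-TTG-5 (-1.63 ± 0.33) and iMet-CAT-3 (-1.62 ± 0.37) had the same sign, with adjusted p of 0.0122 to 0.0135. Gly-GCC-2 had the opposite sign, at 1.34 ± 0.38 (adjusted p = 0.0453), and lost its call in 11 of 24 alternatives. In all, 14 of 179 intestine features passed, 13 of them negative. The count was 25 with RNA samples as a block, 2 with centred libraries, 7 with library totals and 34 in DESeq2. The calls of Met-CAT-5 and Tyr-GTA-5 were lost without treated GF replicate 1, and those of Met-CAT-5, Tyr-GTA-5, Gln-TTG-5 and iMet-CAT-3 with centred libraries. The count was 8 without untreated SPF replicate 2, 22 without untreated GF replicate 1, and 6 and 9 without treated GF replicates 1 and 2. Ser-AGA-2 was the only brain feature to pass, at 1.13 ± 0.21 (adjusted p = 0.035). Its untreated values fell from 327 ± 20.3 kRPKM (SD, n = 3) in SPF to 132 ± 12.7 in GF, and its treated values from 199 ± 18.2 to 176 ± 3.2. Ile-AAT-3 (1.24 ± 0.30) and Ser-CGA-2 (0.82 ± 0.23) followed in brain, at adjusted p of 0.133 and 0.135. With the block or with TMM or RLE, 0 brain features passed. The count was 27 without treated SPF replicate 3 and 17 without treated GF replicate 1, and 0 without each of the other libraries except untreated GF replicate 1. Kidney and liver had 0 calls in limma, with 15 and 19 features at an unadjusted p under 0.05. In kidney, M-Gln-TTG (0.70 ± 0.16), M-Met-CAT (0.86 ± 0.20) and Met-CAT-1 (-0.46 ± 0.14) came closest. The sign of the first 2 turned with scaling: M-Gln-TTG was -0.53 with RLE and -0.62 with TMM, and M-Met-CAT -0.21 and -0.29. In kidney edgeR and DESeq2 called 0, and without treated SPF replicate 1 limma called 2. In liver, Ser-GGA-1 (-3.56 ± 0.89), Met-CAT-5 (-3.44 ± 0.90) and Lys-CTT-14 (-2.81 ± 0.85) came closest, and edgeR with TMM called 2, DESeq2 8 and the block 5. Without untreated GF replicate 2, limma called 4 in liver.

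Tissue differences were examined in treated SPF libraries. Arg-TCT-4 (gene ID 102467638, symbol n-TRtct5) stood out in libraries labelled kidney, at 83.1 ± 14 kRPKM (SD, n = 3), against 15.7 ± 10.3 in liver, 0.144 ± 0.125 in brain and 0.0567 ± 0.0515 in intestine. Against the mean of the other tissues it was 32.9-fold higher in kidney (log2 5.04 ± 0.34, SE; adjusted p = 1.41e-11). Untreated SPF libraries held it at 66 ± 3.91 kRPKM in kidney, 2.6 ± 0.445 in liver, 0.0981 ± 0.0215 in brain and 0.0505 ± 0.0285 in intestine. Brain and kidney libraries carried the same index sequences, and whether their tissue labels were exchanged was not tested. Results for brain and kidney, the long-arm shift and the responses to treatment among them, rest on the labels as given. Kidney was also higher in Ala-TGC-6 (6.69-fold), Thr-CGT-3 (4.37-fold), Thr-AGT-6 (4.10-fold) and Thr-AGT-5 (4.04-fold), and lower in M-Cys-GCA (1.63-fold), whose call was lost in 15 of 23 alternatives. Brain was lower in Val-AAC-4 (5.67-fold), Met-CAT-3 (4.98-fold), Ala-AGC-5 (4.73-fold) and Val-CAC-3 (4.60-fold), and higher in Asn-GTT-1 (3.09-fold), Asn-GTT-3, Ser-CGA-1, M-Leu-TAA and Arg-TCT-1. The brain call of Asn-GTT-1 was lost without brain SPF replicate 3, and those of Asn-GTT-3, Ser-CGA-1, M-Leu-TAA and Arg-TCT-1 without replicate 1 or 2. Intestine was higher in Met-CAT-5 (5.99-fold), Met-CAT-3 (3.24-fold), Gln-TTG-2, Leu-TAG-2 and Lys-CTT-1, and lower in Thr-TGT-1 (5.76-fold), Thr-CGT-4 (3.75-fold), Ala-TGC-6 and M-His-GTG. Without intestine SPF replicate 2, Met-CAT-5, Gln-TTG-2 and M-His-GTG no longer passed. Liver was higher in M-Ser-GCT (3.73-fold), Arg-TCT-4, Arg-TCT-5, Asp-GTC-1 and M-Lys-TTT, and lower in Ser-CGA-3 (4.18-fold), Leu-TAG-2, Leu-CAG-4, SeC-TCA-1 and Leu-CAA-4. Without liver SPF replicate 2, the calls of M-Ser-GCT, Asp-GTC-1, M-Lys-TTT, Ser-CGA-3, Leu-TAG-2, Leu-CAG-4 and Leu-CAA-4 were lost, and without replicate 3 that of Arg-TCT-5.

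**Figure D3:**
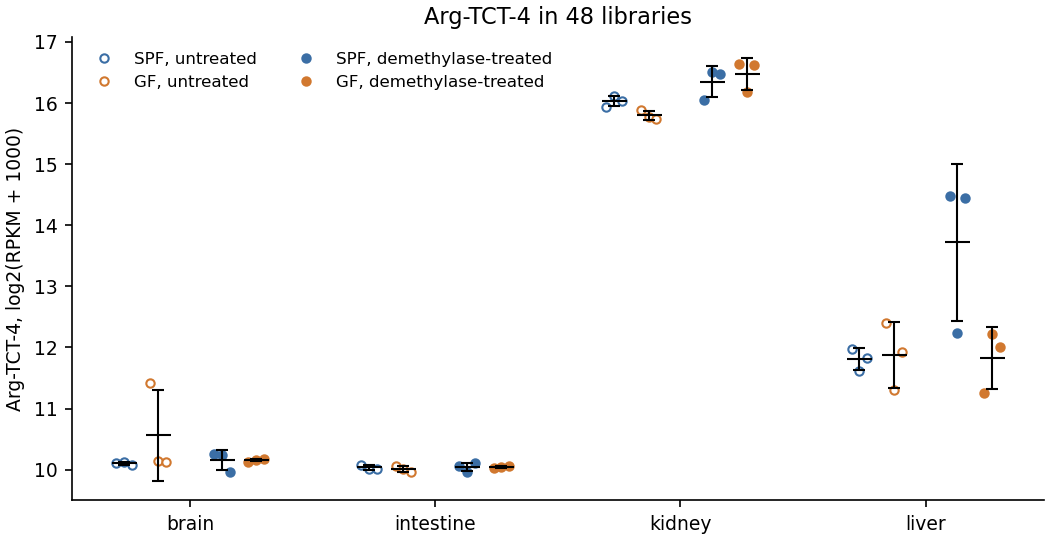
Points are the Arg-TCT-4 values of the 48 libraries in log2(RPKM + 1000), with the mean and SD of each group of 3 as a bar. Libraries labelled kidney lie above those of every other tissue in both treatments, and treated SPF liver spreads widely, at 15.7 ± 10.3 kRPKM.

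Across the 4 tissues, 77 of 188 features differed by the joint test. Ranked by the largest difference of any tissue from brain, Arg-TCT-4 led at 73.1-fold (adjusted p = 4.41e-12). Met-CAT-5 (11.7-fold), Val-AAC-4 (9.90-fold), Val-CAC-3 (8.77-fold) and Ala-AGC-5 (8.55-fold) followed. Brain had 7 features higher and 35 lower than the mean of the other tissues, intestine 22 and 14, kidney 24 and 1, and liver 10 and 15. In brain the sides were 21 and 21 with RLE, 24 and 28 with DESeq2, 30 and 20 with TMM and 14 and 28 with centred libraries. In intestine DESeq2 gave 23 and 24 and centred libraries 18 and 17, in liver RLE gave 10 and 10 and centred libraries 13 and 11, and in kidney centred libraries gave 16 and 3. The joint count was 50 without intestine SPF replicate 1. The brain count was 27 without brain SPF replicate 2, and the intestine count was 18 and 15 without intestine SPF replicates 1 and 2. The liver count was 39 without liver SPF replicate 1 and 9 without replicate 2.

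Whether the GF effect differed between tissues was tested directly in treated libraries, and 10 of 188 features passed. Sizes here are the largest difference of the log2 effect in any tissue from that in brain. Lys-CTT-14 had the largest, 3.21 (adjusted p = 0.0098), followed by Glu-CTC-2 with 2.91 (adjusted p = 0.00667). Met-CAT-3, Leu-CAG-4 and Ser-GGA-1 were at 2.73, 2.64 and 2.53, each with an adjusted p of 0.024. The number of features was 2 with TMM or RLE, 15 in DESeq2 and 1 with centred libraries. It was 2 without brain GF replicate 2, 5 without liver GF replicate 2, and 16 without liver SPF replicate 2 or 3.

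Among lists of tRNAs fixed before the data were examined, serine, leucine and selenocysteine tRNAs, the classes with a long variable arm, were shifted down in GF kidney in treated libraries (median log2 change -0.22 over 29 features; adjusted p = 0.00156, and adjusted p = 0.986 with an estimated correlation). This list was fixed by amino acid, and its member Ser-GGA-1 has a length of 73 nt in the gene list, against 82 to 87 nt for the others. Leucine, proline and arginine tRNAs with m1G37 were shifted up in GF intestine (median 0.17 over 17 features; adjusted p = 0.0368) and down in GF kidney (median -0.25; adjusted p = 0.0392), both with adjusted p = 0.986 at an estimated correlation. The kidney call of m1G37 was lost in 12 of 30 alternatives, among them the replicate block (adjusted p = 0.0552), library totals (0.129) and the fit without the 5 libraries past the midpoint (0.482), and the intestine call in 7 of 30. No member of these lists passed the threshold in those tissues, 0 over all features and 0 adjusted over the list alone, where Ser-GGA-1 (-0.50 ± 0.38, SE), Pro-AGG-1 (0.42 ± 0.31) and Leu-CAG-2 (-0.31 ± 0.28) had the smallest p-values. These were 3 of 44 list tests. Tests by fry, which do not compare a list with other tRNAs, called none of these 3 and instead the essential amino acid, m1G37 and mcm5s2U lists as lower in GF liver (adjusted p = 0.0103, 0.00809 and 0.00809). Adjusted p for the other lists ran from 0.187 to 0.964 for branched-chain and m3C32 tRNAs, 0.214 to 0.964 for initiator methionine, 0.484 to 0.964 for inosine, 0.484 to 0.921 for mitochondrially encoded, 0.511 to 0.964 for essential amino acids, 0.726 to 0.964 for queuosine, 0.921 to 0.964 for Arg-TCT and 0.964 to 0.987 for mcm5s2U tRNAs. Because mitochondrially encoded values are scaled to their own total, that list cannot show a shift of the whole class. With library totals it was higher in GF brain (adjusted p = 0.00136) and lower in GF intestine (adjusted p = 6.28e-16) and GF kidney (adjusted p = 0.000276). Under that scaling the members move with the mitochondrial share of a library, while camera took them as nearly independent. Between treated libraries that share differed by 0.936 points in brain, -7.05 in intestine and -6.55 in kidney. Exact permutation p was 0.2 in intestine, 0.7 in kidney and no smaller in brain, so a shift of the class was not shown. SeC-TCA-1, the only selenocysteine tRNA, was lower in GF by 0.06 ± 0.36 in brain, 0.26 ± 0.36 in intestine, 0.14 ± 0.36 in kidney and 0.37 ± 0.36 in liver (log2, SE; smallest adjusted p = 0.525). Without kidney SPF replicate 3, 0 lists passed. Without intestine SPF replicate 2 or 3 or intestine GF replicate 1, 1 passed, and without brain SPF replicate 3, 5 passed.

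Between treated and untreated libraries, long-arm tRNAs were lower after treatment in brain, where 3 rose and 18 fell of 29, with the same numbers adjusted over the list alone (median -0.66; adjusted p = 0.00031, and adjusted p = 0.894 with an estimated correlation). In kidney 8 rose and 16 fell, or 8 and 17 adjusted over the list alone (adjusted p = 0.0294, and adjusted p = 0.894 with an estimated correlation). The m1G37 list fell in brain (2 rose and 11 fell of 17; adjusted p = 0.0138) and in kidney (3 and 11, or 4 and 11 adjusted over the list alone; adjusted p = 0.0165), both with adjusted p = 0.894 at an estimated correlation. Leu-AAG-1 fell by 1.03 ± 0.14 in brain (SE), while Arg-CCG-1 of the same list rose by 1.01 ± 0.14. The mitochondrially encoded list was shifted down in intestine (4 rose and 16 fell of 22, or 4 and 17 adjusted over the list alone; adjusted p = 0.000798, and adjusted p = 0.894 with an estimated correlation), led by M-Asp-GTC and M-Ile-GAT, with M-Phe-GAA among those that rose. Within a total fixed by scaling, these changes were shifts among mitochondrially encoded tRNAs and do not measure the class as a whole. With library totals the list was lower in intestine (adjusted p = 1.34e-13), liver (adjusted p = 9.33e-24) and kidney (adjusted p = 0.00862), while the authors' scaling gave 0.638 in liver and 0.941 in kidney. Of those 5 calls among 44 tests, fry kept 4, all but the long-arm list in kidney. With treated and untreated libraries paired by a block, 6 list tests passed, those 5 among them. Without the block, the 8 lists without a call had adjusted p no lower than 0.084 for inosine, 0.0927 for initiator methionine, 0.192 for branched-chain, 0.226 for essential amino acids, 0.254 for m3C32 and Arg-TCT, 0.604 for mcm5s2U and 0.693 for queuosine tRNAs. SeC-TCA-1 fell by 1.03 ± 0.32 in liver, 0.79 ± 0.23 in intestine and 0.58 ± 0.16 in kidney (adjusted p = 0.0351, 0.00833 and 0.00462), and its change in brain was 0.00 ± 0.14 (adjusted p = 0.984).

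After the data had been seen, the lists were also tested on GF against SPF in untreated libraries. In brain, all 12 serine and 15 of 16 leucine tRNAs were below 0. Of the 29 long-arm tRNAs, 0 rose and 13 fell, and 13 fell adjusted over the list alone, with a median of -0.43 against 0.33 for all features (adjusted p = 1.18e-10, and adjusted p = 0.000375 with an estimated correlation). Ser-AGA-2, Ser-TGA-2, Ser-AGA-1 and Leu-CAA-2 led this list. Branched-chain tRNAs, which share the leucine members, had 0 rise and 11 fall of 30 in brain (adjusted p = 0.000123, and adjusted p = 0.00563 with an estimated correlation). In kidney the m3C32 list was shifted down with no member past the threshold, led by Thr-AGT-1 at -0.40 ± 0.16 (SE; list adjusted p = 0.00161, and adjusted p = 0.0332 with an estimated correlation). The brain shift differed from the mean of the other tissues (median -0.52 for the list against 0.21 for all features; adjusted p = 6.78e-11 in camera) and from that in treated brain libraries (adjusted p = 1.04e-10). Over these 2 tests, adjusted p was 3.44e-05 and 0.044 with an estimated correlation.

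**Figure D4:**
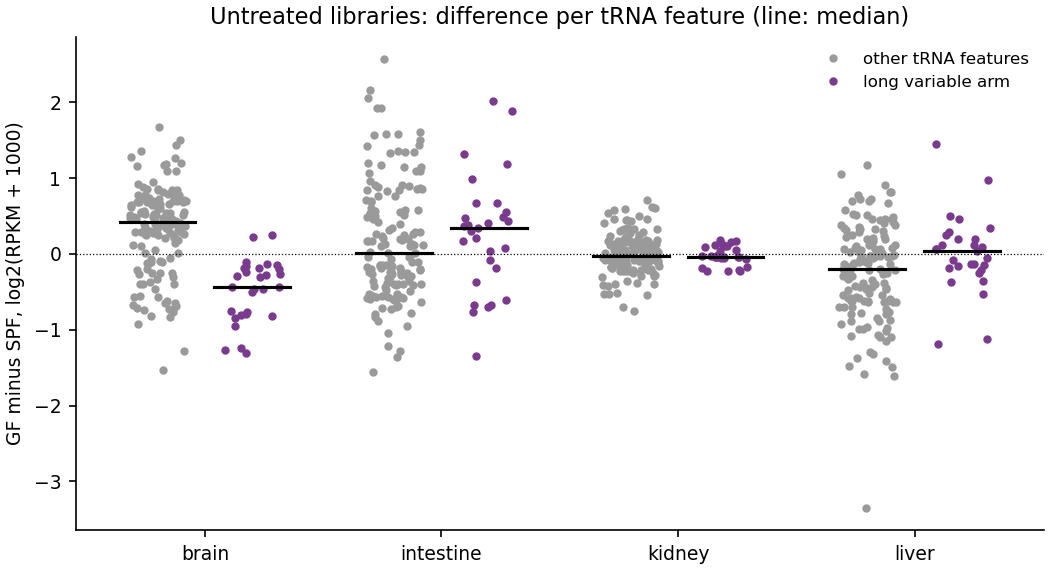
Each point is the GF minus SPF difference of 1 tRNA feature in untreated libraries, in log2(RPKM + 1000), for the 29 features of the long variable arm list and for all others, with medians as lines. In brain the long-arm features lie lower than the others, at a median of -0.43.

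Mitochondrially encoded tRNAs made up a smaller share of molecules in treated libraries, where it fell by 14.3 percentage points on average and was lower in 8 of 8 combinations of tissue and colonization (permutation p = 3e-05; adjusted p = 0.00015 over 5 measures). The share was 17.0% ± 0.913 (SD, n = 3) in untreated SPF brain and 33.3% ± 4.07 in untreated GF brain, and 16.1% ± 12 and 17.0% ± 2.82 in treated brain. In liver it was 56.0% ± 3.19 in untreated SPF and 46.8% ± 4.32 in untreated GF libraries, and 25.0% ± 7.29 and 27.1% ± 21.1 in treated ones. Untreated intestine held 30.5% ± 4.23 in SPF and 41.8% ± 6.03 in GF, and untreated kidney 25.3% ± 3.33 and 30.9% ± 3. Queuosine tRNAs took 1.24 points more of treated libraries (higher in 7 of 8; adjusted p = 0.0004 by permutation). As a share of nuclear-encoded molecules, a measure chosen after the values were seen, they changed by -0.00486 points (higher in 4 of 8; adjusted p = 0.991 by permutation), so the gain did not remain apart from the drop in mitochondrially encoded tRNAs. The effective number of features was 17.8 higher (8 of 8; adjusted p = 0.00015). The number of molecules fell by 7.28 M (M, mega) in treated libraries (permutation test; lower in 7 of 8; adjusted p = 0.0004), and the mapped share of reads fell by 13.8 points (6 of 8; adjusted p = 0.00075).

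Treated GF libraries had a higher mapped share of reads than treated SPF libraries, by 13.8 points on average and from 3.31 in kidney to 26.4 in intestine (higher in 4 of 4 tissues; permutation p = 0.00038; adjusted p = 0.0019). They held 3.33 M more molecules (higher in 3 of 4 tissues; permutation p = 0.0107; adjusted p = 0.0269). Treated SPF intestine and liver libraries carried the same 3 index sequences and had mapped shares of 1.22% to 7.41% and 1.08% to 10.8%. Brain and kidney shared their index sequences group by group. The tissues may thus not be independent strata, and index or library preparation cannot be told apart from colonization in these 2 measures. Without 1 replicate that difference ran from 2.04 M to 3.97 M, and that of the mapped share from 12.6 to 14.5 points. The mitochondrial share (-2.64 points), the queuosine share (0.0981 points) and the effective number of features (-0.091) did not pass, at adjusted p of 0.895, 0.991 and 0.991. In untreated libraries GF exceeded SPF in mitochondrial share by 6.05 points (3 of 4 tissues; permutation p = 0.0351; adjusted p = 0.175). The other untreated measures had adjusted p of 0.22 to 0.835: -0.358 points for the queuosine share, -4.99 for the effective number, 2.25 M for molecules and -8.12 points for the mapped share. The mitochondrial difference ranged from 16.4 points in brain to -9.15 in liver, a range of 25.5 (permutation p = 0.0149; adjusted p = 0.149 over 10 tests). Within 1 tissue, 3 against 3 libraries cannot give an exact two-sided p below 0.1. Without replicate 1 of each group, 0 of the GF measures passed, and without replicate 2 or 3, 1 passed.

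**Figure D5:**
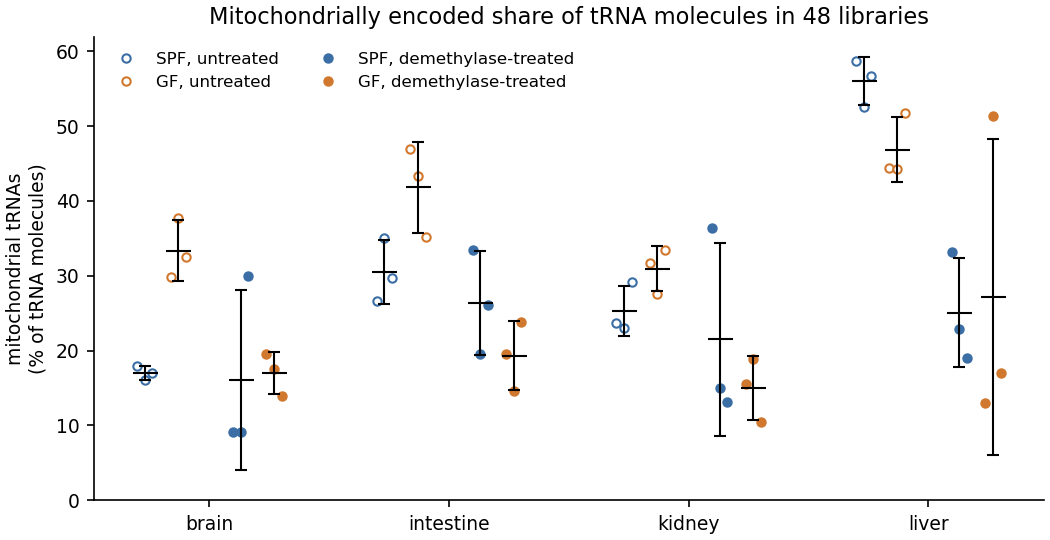
Points give the share of tRNA molecules that are mitochondrially encoded (%) in each of the 48 libraries, by tissue, colonization and treatment, with the mean and SD of each group of 3. The share fell by 14.3 points on average in treated libraries, and untreated GF brain (33.3%) lies above untreated SPF brain (17.0%).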

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

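The tests of GF replicate 2 and of the scaling in liver, of treated material in untreated intestine, of the long-arm list in untreated libraries with its 2 differences, and the comparison of responses between tissues were chosen only after the results were seen.

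In treated liver, 41 features were lower in GF and 0 were higher. With the 6 libraries thinned to the 25798 molecules of the shallowest, the median over 20 thinnings was 40 calls (35 to 46). The medians were 38.5 lower and 35 shared with the 41. This argues against the difference in molecules counted as the cause of the lower calls. Thinning cannot mimic other traits of shallow libraries. Without GF replicate 2, whose profile resembled untreated libraries, 25 of the 41 features remained called and lower among 30 calls. Without SPF replicates 2 and 3, 36 and 38 remained, and without GF replicates 1 and 3, 35 and 33. Without SPF replicate 1, which did not resemble untreated ones, 19 remained among 20. A part played by GF replicate 2 is therefore not settled. With each library centred at its median 17 features were called, 14 of them lower, so the authors' scaling may contribute. The test pooled the spread of all 8 groups, while treated liver replicates correlated at only 0.812 to 0.961. A fit to the 6 liver libraries alone called 5 features, so the pooled estimate may contribute too. An effect of colonization itself stays open and was not tested apart from these.

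Untreated GF intestine libraries lay nearer the treated profile than SPF ones, with a gap of 0.89 between the mean scores. Thinning to 223773 molecules left a median gap of 0.89 (0.87 to 0.89), which argues against counting error alone. It cannot mimic other traits of shallow libraries, so depth stays open. Within GF the score fell from 0.77 at 16331640 molecules to 0.58 at 2074440 and 0.31 at 223773. Within SPF it was 1.59 at 17761532, 1.50 at 15915187 and 1.23 at 3482600. Treated material in the GF libraries cannot be told apart either: their mitochondrial share averaged 41.8% against 30.5% in untreated SPF and 19.3% in treated GF libraries, but it fell with the score, from 46.95% (score 0.77) to 43.28% (0.58) and 35.17% (0.31), and the share of GF libraries free of such material is unknown. Less methylation in GF intestine cannot be told apart from other causes: across features, which are not independent, the GF difference correlated at -0.43 with the treatment response of the other 3 tissues, a sign opposite to that needed, but other splits of the 6 libraries reached 0.45 in size and the response of intestine itself ran against that of brain and kidney (r = -0.40). Colonization stays open as a biological source, untested by these values.

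In untreated brain, the 29 tRNAs with a long variable arm were shifted down in GF (median -0.43 against 0.33 for all features; list adjusted p = 1.18e-10 in camera, and 0.000375 with an estimated correlation). Thinning to 3973164 molecules gave a median adjusted p in camera of 1.25e-10 (1.02e-10 to 1.4e-10), which argues against counting error alone. Every library already held at least that many molecules, so thinning could change little and cannot address other traits of the libraries. The mapped share of reads was 15.3% to 30.4% in GF and 26.9% to 30.6% in SPF. Leaving out GF replicate 1, which had an intermediate score, gave an adjusted p of 1.25e-08, within a range of 2.81e-12 (library totals) to 0.000375 (estimated correlation) over the alternatives, which argues against that library as the only source. A loss of longer molecules cannot be told apart: over 148 features outside the list the Spearman correlation of the change with length was -0.02 (permutation p = 0.779) and -0.18 for nuclear-encoded ones, but those features span only 59 to 75 nt while the list reaches 87, and within the list the longest, SeC-TCA-1, did not fall (0.22 ± 0.26, SE) while Ser-GGA-1 of 73 nt was below 0, too few to decide. An effect of colonization stays open and untested.

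The long-arm shift in untreated brain differed from the mean of the other tissues (adjusted p = 6.78e-11 in camera, and 3.44e-05 with an estimated correlation) and from the shift in treated brain libraries (adjusted p = 1.04e-10, and 0.044 with an estimated correlation). The response to treatment differed between GF and SPF for 14 intestine features by the interaction term, among them Gly-GCC-2 (1.34), Met-CAT-5 (-2.54), Tyr-GTA-5 (-1.95), Leu-CAA-4 (-1.85), Gln-TTG-5 (-1.63) and iMet-CAT-3 (-1.62) on the log2 scale. That count was 8 without untreated SPF replicate 2, 22 without untreated GF replicate 1, and 6 and 9 without treated GF replicates 1 and 2. In brain the interaction term singled out 1 feature, Ser-AGA-2 (1.13), and the count was 27 without treated SPF replicate 3, 17 without treated GF replicate 1 and 0 without 9 of the other 10 libraries. The effect of GF in treated libraries differed between tissues for 10 features by the joint test. The largest difference of the log2 effect from that in brain was 3.21 for Lys-CTT-14, 2.91 for Glu-CTC-2 and 2.73 for Met-CAT-3. It was 2.64 for Leu-CAG-4 and 2.53 for Ser-GGA-1. Without brain GF replicate 2 the joint test called 2 features, without liver GF replicate 2 it called 5, and without liver SPF replicate 2 or 3 it called 16. In 19 features the response to treatment had 1 sign in every RNA sample of intestine and the opposite sign in every RNA sample of brain and kidney. At most 14 did over the 31 other sign flips of the intestine samples. Any steady response of intestine makes the real count the largest, since flips break the agreement of its samples. The flips therefore do not test whether the response was opposite to that of brain and kidney.

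Other splits of the libraries were fitted to see how often a regrouping gave as many calls as the real one. The real grouping is counted among the splits in each case. For treated against untreated libraries the real count was the largest of 32 splits that parted the treated and untreated library of every RNA sample. It was 118 against at most 61 in brain, 105 against 79 in intestine, 154 against 136 in kidney and 36 against 30 in liver. Chance is thus unlikely for each, though the margins in kidney and liver were narrow. Over 100 groupings for the tissue differences, the real counts and the highest others were 77 and 25 in the joint test and 42 and 32 for brain. They were 36 and 12 for intestine, 25 and 24 for kidney, and 25 and 35 for liver. Only in liver was a regrouping as large, with 2 of the 100 counting the real one, so chance is unlikely but not excluded there. For the effect of GF differing between tissues, 3 of 100 groupings were as large, and a regrouping called more than the real one (11 against 10). Chance is unlikely there but not excluded. For the lists chance stays a ready explanation, since 40 of 100 groupings gave as many lists for GF against SPF (3 against 9) and 45 of 100 for treated against untreated (5 against 11).

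The 10 splits of 3 against 3 are too few for a share under 0.05. In treated GF against SPF libraries the real count and the highest other were 41 and 23 in liver and 0 and 0 in brain, intestine and kidney. By anticodon they were 7 and 7 in liver, with 2 splits as large counting the real one, and 0 and 0 elsewhere. In untreated libraries they were 67 and 0 in brain, 78 and 2 in intestine, 1 and 0 in kidney, and 43 and 39 in liver. For the interaction with treatment they were 1 and 0 in brain, 14 and 0 in intestine, and 0 and 0 in kidney and liver.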

How the results depend on the processing

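TMM factors, pseudocounts of 100 and 5000 RPKM, centred libraries, array weights, the mitochondrial total of the mapping table, the queuosine share of nuclear-encoded molecules and leaving out the 5 libraries past the midpoint toward the other treatment state were chosen after seeing the data.

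Over all alternatives, 548 of 684 counts of called features, lists or measures stayed within 1.5 times the reported count and 136 moved further. Of 3869 comparisons for single features, lists and measures, 3512 kept their direction and their side of the threshold, 281 lost a call, 61 gained one and 15 reversed, and 87 of the 176 single results kept theirs in every alternative run on them. Treated against untreated counts stayed at 105 to 157 in brain, 85 to 135 in intestine and 137 to 185 in kidney. Of the 5 measures that differed with treatment, 4 passed in every alternative. The gain of 1.24 points in queuosine share became -0.00486 points (adjusted p = 0.991) as a share of nuclear-encoded molecules. Treated GF against SPF intestine had 0 calls under every alternative for features and for anticodons, in limma, edgeR and DESeq2, with 0 at an unadjusted p under 0.05. That is fewer of 188 features than expected without any change, so limma may be conservative there. The comparison was not simulated and its SPF libraries held 70051 to 544433 molecules, so changes could have been missed. The counts of measures, the only counts on which these settings were run, were unchanged at 2 and 5 with a minimum mean count of 10 and with the mitochondrial total of the mapping table.

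Camera with an estimated correlation left 0 of the 3 lists for GF against SPF and 0 of the 5 for treatment, so none of the 8 list calls held in camera once the correlation was estimated. Fry, which does not compare a list with other tRNAs, called 28 lists for treatment and kept 4 of the 5 treatment calls and 0 of the 3 for GF. Library totals gave 6 lists for GF and 11 for treatment. A difference of medians left 1 of the 2 GF measures.

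For the counts that follow, the cause was not tested. Array weights raised GF against SPF in treated libraries from 0 to 71 in brain and from 0 to 4 in kidney, and by anticodon from 0 to 29, from 0 to 5, and in liver from 7 to 12. In untreated libraries they raised it from 67 to 125 in brain, 1 to 51 in kidney and 43 to 74 in liver. They gave 107 for treatment in liver (reported 36), and for the interaction with treatment 99 in brain (1), 25 in intestine (14), 6 in kidney (0) and 5 in liver (0). Tissue differences rose from 77 to 165 with them, brain from 42 to 137, intestine from 36 to 96, kidney from 25 to 91 and liver from 25 to 67, and the GF effect differing between tissues from 10 to 53.

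Scaling moved liver most often. Treated GF against SPF liver gave 25 calls with RLE, 24 with TMM and 17 with centred libraries, against 41, and its anticodons 1 with TMM and 3 with centred libraries, against 7. Treatment in liver, at 36, gave 64 with RLE, 62 with TMM, 108 with library totals, 75 with DESeq2 and 21 with centred libraries. The interaction in liver, at 0, gave 2 with each of RLE, TMM and library totals and 8 with DESeq2. In brain, at 1, it gave 0 with RLE and TMM and 5 with DESeq2, and in intestine, at 14, it gave 7 with library totals, 34 with DESeq2 and 2 with centred libraries. Liver against other tissues fell from 25 to 11 with library totals. The GF effect differing between tissues, at 10, was 2 with RLE and TMM and 1 with centred libraries. Untreated kidney, at 1, was 0 with centred libraries.

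Without the filter on low values untreated kidney had 2 calls and treatment in liver 17. The replicate block gave 0 in untreated kidney, and for the interaction 0 in brain, 25 in intestine and 5 in liver, and 4 for the GF effect differing between tissues. With pseudocounts of 100 and 5000 the interaction in intestine was 23 and 9, and with 5000 the GF effect differing between tissues was 4. Leaving out mitochondrially encoded tRNAs left 0 in untreated kidney, where the called feature was mitochondrially encoded.

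Fits to 1 tissue alone gave 5 calls in treated liver, 44 in untreated kidney and 9 in untreated liver, and by anticodon 2 in brain and 2 in liver. With the libraries past the midpoint also left out, such fits gave 12 in treated brain, 1 in treated liver, 48 in untreated intestine (reported 78) and 44 in untreated kidney, and by anticodon 21 in brain, 3 in kidney and 0 in liver. These fits use fewer libraries. In the joint fits, leaving out those 5 libraries gave 2 in untreated kidney, 83 for treatment in liver, and for the interaction 27 in brain and 2 in kidney. Tissue differences became 116, intestine against other tissues 75 and liver against other tissues 51, the GF effect differing between tissues 4, and 1 of the 2 GF measures passed.

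Leaving out 1 library at a time moved 54 of 330 counts. The ranges were 20 to 56 for treated liver, 44 to 63 for untreated brain, 0 to 0 for untreated kidney, 26 to 60 for untreated liver, 5 to 12 for anticodons in liver and 13 to 57 for treatment in liver. For the interaction they were 0 to 27 in brain, 6 to 22 in intestine, 0 to 2 in kidney and 0 to 4 in liver. Tissue differences ran from 50 to 92, brain from 27 to 54, intestine from 15 to 50 and liver from 9 to 39, and the GF effect differing between tissues from 2 to 16. The lists for GF ran from 0 to 5 and the GF measures from 0 to 1. Where a group was left with 2 libraries, they were taken to vary like the other groups. Of 1820 single results, 140 lost a call, 8 gained one and 4 reversed.

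DESeq2 gave no adjusted p for Met-CAT-5 in the treatment comparison in kidney. The queuosine share above was the only result past the threshold that reversed. In kidney the interaction of M-Gln-TTG (reported 0.70) was -0.53 with RLE and with DESeq2, -0.62 with TMM and -0.13 with library totals, and that of M-Met-CAT (0.86) was -0.21, -0.21 and -0.29 with RLE, DESeq2 and TMM. In treated libraries without replicate 1 of each group, the GF difference became 1.61 points for the mitochondrial share (-2.64) and -0.534 points for the queuosine share (0.0981), and without replicate 2 it became 6.44 for the effective number of features (-0.091). Over the 3 replicates left out, these ran from -8.43 to 1.61, from -0.534 to 0.553 and from -4.99 to 6.44. As a share of nuclear-encoded molecules, the GF difference of queuosine tRNAs was -0.215 points in treated and 0.15 points in untreated libraries (-0.358). The difference in molecules of untreated libraries (2.25 M) was -3.65 M for medians, and -2.76 M to 6.28 M without 1 replicate. The cause was not tested.

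Depth limits treated SPF liver and intestine most, at 25798 to 197369 and 70051 to 544433 molecules, where a feature named in treated liver averaged 203 to 415 molecules per library. In simulated counts of treated brain, 6 of 20 changed features were recovered at 2-fold, so a count of 0 there does not exclude changes of that size.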

Other observations

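All tests given here were chosen only after the result was seen, and correlations run across 184 features, which are not independent replicates. Treated and untreated libraries were paired by replicate number, a link that the residuals of intestine libraries did not show.

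The response to treatment (treated minus untreated, log2) in intestine ran against the mean response of brain and kidney, with r = -0.40 (Spearman -0.41). The range was -0.44 to -0.36 with 1 RNA sample left out, and the values were -0.44 in SPF and -0.27 in GF. An exact sign-flip test over the 6 RNA samples of intestine gave p = 0.344 (adjusted 0.459 over 4 tests, smallest possible 0.0312), so the correlation did not pass. Brain and kidney correlated at 0.90 (exact sign-flip p = 0.156 for brain and 0.125 for kidney, adjusted 0.312 for each), so this test did not pass there either. Liver was at -0.01 against brain and kidney. In 19 of the 184 features the 6 intestine samples had 1 sign and the 12 brain and kidney samples the other, 8 higher and 11 lower in intestine, while 3 features had the same sign in all 18. Over the 31 other sign flips of the intestine samples, at most 14 features were opposite. Flips break the agreement of the intestine samples whichever way they respond, so this does not test opposition.

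Features with the widest opposition, chosen after their values were seen, were M-His-GTG at -1.48 ± 0.38 (SD, n = 6) in intestine and 2.13 ± 0.92 (SD, n = 12) in brain and kidney, iMet-CAT-1 at -1.75 ± 0.56 and 1.85 ± 0.54, Asn-GTT-3 at -1.06 ± 0.49 and 2.16 ± 0.63, Tyr-GTA-5 at 1.65 ± 1.17 and -1.22 ± 0.66, and Val-CAC-2 at -1.39 ± 0.4 and 1.26 ± 0.41.

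A hypothesis is that treated and untreated labels were exchanged in intestine, where the mitochondrial share fell by 13.3 points in libraries labelled treated (lower in 5 of 6 RNA samples; exact sign-flip p = 0.0938), which did not settle it. Mitochondrial molecules per mapped mitochondrial read were higher in treated libraries of the other tissues, in 5 of 6 RNA samples of brain, 6 of 6 of liver and 5 of 6 of kidney, or 4 of 6 of kidney with the mapping table total of treated GF replicate 1. In intestine libraries labelled treated they were also higher, by 0.288 on average and in 6 of 6 RNA samples, at 0.958 to 1.01 against 0.622 to 0.813 (exact sign-flip p = 0.0312, the smallest possible). An exchange of all labels needs the reverse, so this argues against it, although how reads became molecules is not given. Shallow treated libraries may have distorted the response and cannot be told apart from other causes: the deeper GF treated libraries had r = -0.27, and at most -0.12 with 1 RNA sample left out, but the test over all 6 samples did not pass (exact sign-flip p = 0.344). The index set shared by intestine and liver could also have contributed: the response of liver had r = -0.25 with brain and kidney in SPF but 0.37 in GF, and since tissue and index set coincide, this cannot be told apart from tissue.

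Between groups, the responses of brain and kidney correlated at 0.80 to 0.92, those of SPF and GF intestine at 0.79 and those of SPF and GF liver at 0.40. The GF minus SPF difference in untreated libraries correlated with that in treated ones at 0.67 in brain, 0.31 in intestine, 0.24 in kidney and 0.08 in liver. Other splits of the same libraries reached 0.67, 0.44, 0.52 and 0.53 in size, and the 10 splits are too few for a share under 0.05.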
